A study of Homo sapiens with 4 samples.

How the data were processed

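RNA of 4 MCF12A cultures was hybridised to 4 Affymetrix Human Gene 1.0 ST arrays: control 1, ethanol (25 mM, 1 week), control 2 and acetaldehyde (2.5 mM, 1 week). Groups and the pairing of each exposure with its control were taken from the sample labels. Per the labels' protocols, cells were grown in medium with horse serum, epidermal growth factor, hydrocortisone, insulin and cholera toxin, and RNA was extracted with a column kit and labelled with biotin. The labels also mention longer exposures, growth in soft agar and microRNA assays, which were not analysed here.

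The authors deposited 1 intensity per probe set and array, on a linear scale, and the submitters' processing notes name RMA, the usual background correction, quantile normalization and probe summary for these arrays. Its software and version are not given in the sources used here. The deposited intensity values ran from 3.13 to 22858, whereas the planned tests took values on a log2 scale, so log2 was taken first, with no offset. Identical values were found for 77 probe sets in the ethanol pair and 38 in the acetaldehyde pair, against 0 or 1 in each pair of arrays from different experiments, and with the distributions given in the results this points to separate normalization of the pairs by the authors. Differences within a pair set no array of one experiment against the other, although normalizing all 4 arrays again changes them. Arrays carry no read depth, and the number of arrays and signal near background limit the precision stated.

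Of 33297 probe sets, the platform annotation used here gave 1 gene symbol for 19460 and several for 1754, and 12083 were not named there. For 19429 of the 19460 the gene identifier matched the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols and was used only for names, RNA classes and neighbouring genes. Probe sets with several symbols or none were left out of gene comparisons. For 769 of 18417 genes with several probe sets the one with the highest mean was used. A gene was kept if its highest value on the 4 arrays reached the median of all gene-naming values (log2 7.28, intensity 155), which left 10373 genes. No other arrays entered, the deposited values having 0 columns of other samples.

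With 1 array against 1, the matched comparisons have no test. They count genes at least 2-fold apart whose exposed value lies outside the range of both controls. To give the count under the spread between the controls, control 1, control 2 and 1 exposed array were simulated 100 times. Each was drawn around the gene's mean over all arrays with the spread of the controls and no change from exposure. The overlap of the exposures was also computed by size alone, and under the range rule with control 2 and acetaldehyde exchanged at random in each gene (100 times), both added after the data were seen. Tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8) with Benjamini-Hochberg adjustment at 0.05: either exposure against controls with the experiment as a block, and each exposure against both controls. Each fit leaves 1 residual degree of freedom. Nothing in the labels says more than that the controls are separate cultures of separate experiments, so p-values measure the spread between these arrays. The blocked fit takes the difference between the responses as its error, and ethanol and acetaldehyde are not replicates of one treatment.

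The main tests, most alternatives, the rule for named genes and 31 gene lists were fixed before the data were examined; what was added later is named as such. The lists cover ethanol and aldehyde metabolism, NRF2, metallothioneins, unfolded protein response, ATF4, heat shock, p53, Fanconi and homologous recombination, proliferation, replication histones, cholesterol, fatty acids, NF-kB, interferon, mesenchymal, luminal, basal, squamous and non-epithelial markers, hypoxia, aryl hydrocarbon and retinoid targets, immediate early genes, YAP, Notch, Wnt, one-carbon metabolism, mitochondrial respiration, ribosomal proteins, apoptosis and growth factors. Each list was summarised by the median matched difference, its percentile among 10000 random lists matched in 20 bins of mean expression, camera (preset correlation 0.01) and fry in limma. The named genes are the 10 largest differences in each direction outside both controls for each exposure, the 5 largest between controls and between responses, the 5 smallest p in each direction for each fit in which fewer than 5 passed, and up to 4 members per list with the largest difference; the other members named, such as IVL, KRT4, KLK7, KRT1, S100A7, SPRR2A and SERPINB3, were chosen after their values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

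The steps were tested on simulated data of 10373 genes. For the blocked fit, limma called 64 of 100 genes changed by 1 log2 unit and 100 of 100 changed by 3, with 6 false calls. For the ethanol comparison, 55% of genes changed by 1 and 100% of genes changed by 3 were at least 2-fold apart, beside 51 unchanged genes. For the lists, a list of 25 genes shifted by 0.5 stood at percentile 100, and 0 of 20 unshifted lists passed camera. Noise was drawn independently for each gene, and both exposed arrays were given the same change. In the data the estimated correlation was 0.681 in the squamous and 0.778 in the histone list, and the slope of acetaldehyde on ethanol was 0.18. The simulations therefore check the steps but do not show error rates or power for these arrays. Alternatives covered the size threshold, the dim filter, the control used, the range rule, median centring, quantile and cyclic loess normalization, all probe sets, the eBayes prior, the experiment block and leaving out each array.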

Results

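Gene expression was measured in MCF12A cells, an established non-tumorigenic human breast epithelial cell line, grown as monolayers and exposed for 1 week to 25 mM ethanol or to 2.5 mM acetaldehyde, the first product of ethanol oxidation. The series held 4 Affymetrix Human Gene 1.0 ST arrays, which read transcripts with many short probes along each gene. There was 1 ethanol array with its own unexposed culture (control 1) and 1 acetaldehyde array with its own unexposed culture (control 2). The median intensity over 33297 probe sets was 92.2 in control 1, 90.2 with ethanol, 113.8 in control 2 and 113.0 with acetaldehyde. The value distributions differed by a mean of 0.0398 (log2) within the ethanol pair and 0.0268 within the acetaldehyde pair, against 0.270 to 0.285 between arrays of different pairs, so the pairs appear to have been normalized separately. Differences below are therefore log2 differences between an exposed array and its own control, over 10373 kept genes, unless another comparison is named. With 1 array per arm these differences have no replicate check, and the number of arrays limits their precision.

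The first comparison asked which transcripts differed after 1 week in ethanol. Of the 10 lowest genes outside the range of both controls, SPRR3, SPRR1A, SPRR1B and KRT10 belong to the squamous differentiation list. SPRR3 (probe set 7905548), a small proline-rich envelope protein, was 71.3-fold lower, at an intensity of 61.8 with ethanol against 4404 in control 1. SPRR1A was 34.6-fold lower and SPRR1B 21.1-fold lower, while KRT10 (probe set 8015104), the keratin of suprabasal cells, was 18.4-fold lower, at 70.5 against 1298. The ceramide synthase CERS3 was 22.5-fold lower, the peptidoglycan recognition protein PGLYRP3 19.2-fold lower and the calcium-binding protein CALB1 17.7-fold lower. The highest of these genes were TGM2 (probe set 8066214), tissue transglutaminase, at 5.66-fold, the pattern recognition receptor TLR2 at 5.40-fold, ANGPTL4, a secreted inhibitor of lipoprotein lipase, at 5.08-fold, and the protease inhibitor SERPINA1 at 4.59-fold.

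Among the other large differences with ethanol, the protease inhibitor SPINK7 was lower by a log2 difference of -5.29, the actin-binding POF1B by -4.38 and the lipid-binding family member BPIFC by -4.21. The adhesion molecules NRCAM, CDH11 and MCAM were higher by 1.89, 1.82 and 1.68, the prostaglandin transporter SLCO2A1 by 1.89, the sulfate transporter SLC26A2 by 1.67 and the cytokine receptor IL31RA by 1.58. The protease inhibitor TFPI2, named after its value was seen, was higher still at 2.55, but its intensity of 1193 lay between those of control 1 (204) and control 2 (2399). In total, 234 genes were at least 2-fold apart and outside the range of both controls, of which 88 were higher and 146 lower. The balance turned at a 1.5-fold threshold (398 higher, 294 lower) and against the other experiment's control (365 higher, 264 lower). Control 2 was itself at least 2-fold below control 1 for 80 of these 146 lower genes (54.8%), against 13.1% in simulations with the controls' spread, and at least 2-fold above it for 10 of the 88 higher genes (11.4%), against 13.2%. Sizes are least certain where a value lay below the filter intensity of 155, as with ethanol for SPRR3, KRT10, CERS3, PGLYRP3 and POF1B, and for SPINK7 (9.28) and BPIFC (21.3), which lay below that array's lower quartile of 29.7. For SPRR3 the intensity was 162 in control 2, and for TGM2 it was 1275, close to the 1451 measured with ethanol. The same simulations gave a mean of 244 lower and 243 higher genes under the same rule, but their spread is that between separately normalized experiments, and the spread of an unchanged pair within 1 experiment was not measured.

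**Figure D1:**
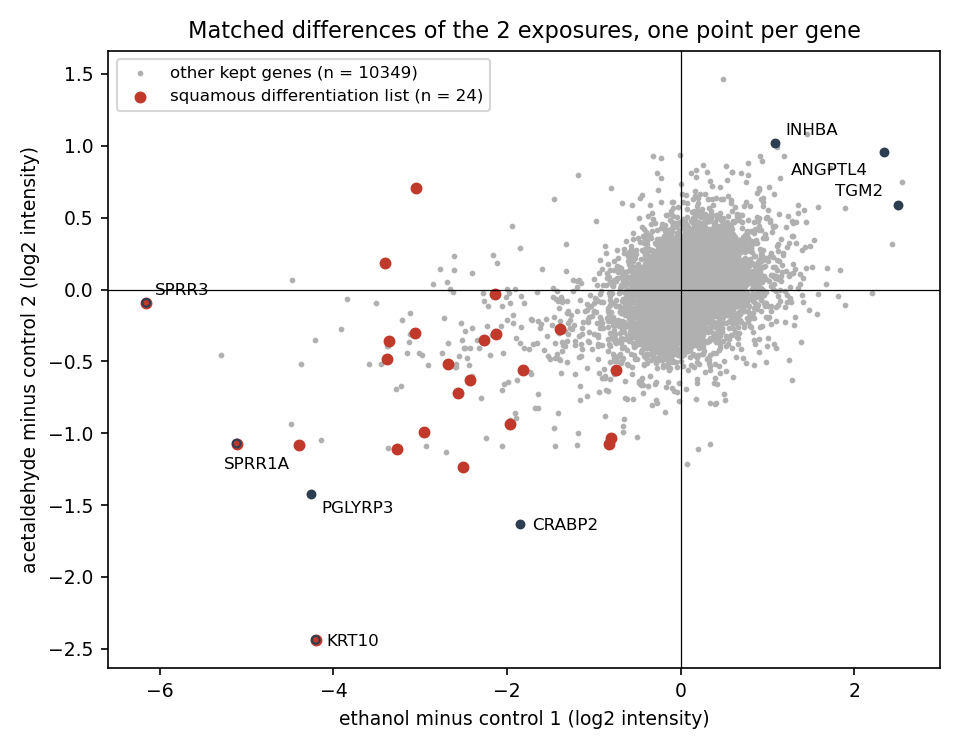
Log2 intensity difference of ethanol minus control 1 (horizontal axis) against acetaldehyde minus control 2 (vertical axis) for 10373 kept genes, with the 24 squamous differentiation genes in red. The red points lie left of 0 for all 24 genes and below 0 for 22 of them.

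The squamous differentiation list, fixed beforehand, had 24 kept genes, and all 24 were lower with ethanol, with a median of -2.62, below all 10000 random lists of matched expression. Of these, 16 were at least 2-fold lower and below both controls, among them SPRR1A, SPRR1B, KRT10 and PI3 (elafin, a protease inhibitor of stressed epithelium, 9.62-fold lower). The same list was also lower in control 2 than in control 1, with a median of -1.67, likewise below all 10000 random lists. This comparison shares control 1 with that of ethanol. Members such as IVL (involucrin, -1.77), KRT4 (-2.75) and KLK7 (-3.68) differed between the controls by more than 1 log2 unit. Control 2 lay within 0.64 of control 1 for LCN2 (0.27), KRT10 (0.28), S100A9 (0.38), PI3 (-0.39) and KRT16 (-0.64), and above it for S100A8 (0.82), KRT1 (1.29) and S100A7 (1.84). The basal or myoepithelial list, with 13 kept genes, had a median of -0.20 and went both ways, since DSG3, a desmosomal cadherin, was at -1.16 and KRT14 at -0.66, whereas LAMB3, a laminin chain, was at 1.35. The luminal list (13 genes) had a median of -0.15, with CD24 at -1.14, EPCAM at 0.70 and KRT8 at 0.75. The mesenchymal list (14 genes) was higher, with a median of 0.59 and 11 genes above control 1, including fibronectin FN1 (2.52-fold), the gelatinase MMP2 (2.45-fold), tenascin TNC (2.14-fold) and the transcription factor ZEB1 (2.04-fold). Control 2 was 0.77 above control 1 over this list, and FN1 was 12-fold higher in control 2 than in control 1. Against the other experiment's control the medians turned to -0.28 for the mesenchymal, 0.88 for the luminal and 0.12 for the basal list, and without the dim filter the basal median turned to 0.0855.

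Cell-cycle transcripts were higher with ethanol for 32 of the 34 genes of the proliferation list, with a median of 0.37, including the kinesin KIF20A (1.40), the centromere protein CENPF (0.92) and cyclin CCNB2 (0.70). All 18 kept replication-dependent histone genes were lower, with a median of -0.39 and H4C8 lowest at -1.41. Of 26 antioxidant genes of the NRF2 list 19 were higher (median 0.42), led by the glutathione synthesis enzyme GCLC (1.23), the export pump ABCC2 (1.17) and AKR1C3 (1.15), whereas the cystine transporter SLC7A11 was at -1.18. Of the metallothionein list, metal-binding proteins and a zinc exporter, 9 of 10 were higher (median 0.40), with MT1F at 1.16 and MT1X at 1.10. In the ATF4 amino acid response list 18 of 21 genes were lower (median -0.55), including CHAC1 (-1.70), STC2 (-1.33) and TRIB3 (-0.93). Control 2 differed from control 1 in the same direction as ethanol in each of these lists, with medians of 0.19 for proliferation, 0.75 for NRF2, 0.25 for metallothioneins, -0.62 for histones and -0.89 for ATF4. Both differences subtract control 1, so a deviation of that array alone would give the same direction in both. KIF20A (2.07), CENPF (1.70) and CCNB2 (0.80) differed more between the controls than with ethanol. Against the other experiment's control the ethanol medians turned to -0.35 for NRF2, -0.0242 for metallothioneins, 0.26 for histones and 0.25 for ATF4.

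Besides the squamous list, 10 lists had ethanol medians in the lowest or highest 1% of matched random lists: mesenchymal, NRF2 and proliferation (each at percentile 100), metallothioneins (99.96), YAP (99.4), ATF4 and histones (each at 0), basal (0.020), ribosomal proteins (0.475) and immediate early genes (0.700). Control 2 against control 1, with no exposure, put ATF4, histones and cholesterol at 0 and NRF2, mesenchymal and immediate early genes at 100. Proliferation (98.8), YAP (94.2), metallothioneins (86.3), basal (82.4) and ribosomal proteins (48.8) were less extreme there. An extreme percentile thus does not by itself set exposure apart from a difference between cultures. Control 1 enters both the ethanol and the control comparison, so extremes that they share can come from that array alone. The medians were 0.21 for the unfolded protein response (19 genes; PDIA4 0.82, DDIT3 -0.76), 0.21 for heat shock (13 genes; HSPH1 0.73), 0.17 for p53 targets (21 genes; ZMAT3 0.89) and 0.16 for Fanconi and homologous recombination genes (17 genes). ATF4, in the unfolded protein list, had 2 probe sets that disagreed, at -0.71 and 0.43. YAP targets had a median of 0.28 (15 genes; CCN2 1.48, F3 -0.98), Wnt genes 0.22 (13 genes; the Wnt antagonist DKK1 1.09), interferon response 0.24 (10 genes; OAS1 -1.15) and NF-kB inflammation 0.19 (13 genes; IL6 1.23, IL1B -1.46). Ethanol and aldehyde metabolism had a median of 0.04 over 11 genes, with the aldehyde dehydrogenases ALDH3B2 at -2.60 and ALDH7A1 at 0.63. Fatty acid synthesis had a median of -0.01 and a mean of 0.26 over 14 genes, with the desaturase FADS1 at 1.31, and cholesterol synthesis had a median of -0.06 over 19 genes, with MVD at -0.72. Medians for Notch (16 genes; NOTCH3 -1.40, NRARP -1.37), growth factor signalling (20 genes; ERBB3 -1.40), one-carbon and methylation genes (14 genes; TET2 -0.83) and hypoxia and glycolysis (17 genes; EGLN3 -1.28) were -0.04, -0.04, -0.04 and -0.07. Mitochondrial respiration (26 genes) was at 0.10, apoptosis regulators (14 genes) at 0.08, ribosomal proteins (25 genes) at -0.06, retinoid targets (5 genes) at -0.05, immediate early genes (14 genes) at -0.11 and aryl hydrocarbon targets (4 genes) at -0.24. The median turned to -0.0843 for YAP, 0.53 for cholesterol and 0.38 for hypoxia against the other experiment's control, and to -0.0720 for Wnt without the dim filter. Of the 20 listed markers of non-epithelial cells only CD14 (0.60), CD68 (0.12) and DCN (-0.01) were bright enough to be kept.

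The acetaldehyde comparison addressed the metabolite of ethanol at its own dose. Among genes outside the range of both controls, the lowest was KRT10, 5.42-fold lower, at 290.0 against 1571 in control 2. CRABP2 (probe set 7921099), a cellular retinoic acid binding protein, was 3.10-fold lower, PGLYRP3 2.68-fold and the stress keratin KRT16 2.36-fold. TNFSF10, the death ligand TRAIL, was 2.32-fold lower, IL1RN, the interleukin-1 receptor antagonist, 2.19-fold, the kinase SGK1 2.16-fold, SERPINB13 2.15-fold and the homeobox gene DLX5 2.13-fold. The highest were the small Cajal body RNA SCARNA9 at 2.12-fold, INHBA (probe set 8139207), the activin A subunit, at 2.03-fold, ANGPTL4 at 1.94-fold and SUGCT at 1.91-fold. The zinc finger gene ZNF814, named after its value was seen, was higher by 1.47, at 97.2 against 35.2 in control 2, but below the 111 of control 1. SCARNA9L is a close copy of SCARNA9, so its 1.91-fold value is uncertain.

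In total, 20 genes were at least 2-fold apart and outside both controls with acetaldehyde, 2 higher and 18 lower. With all probe sets, including those that name no gene, the balance turned to 83 higher and 22 lower. Probe sets with no or several named genes made up 81 of the higher and 4 of the lower ones. Of the 24 squamous genes 22 were lower, with a median of -0.56, below all 10000 matched random lists, and 5 were at least 2-fold lower and below both controls. SPRR2A (0.70) and SERPINB3 (0.18) were the 2 members above control 2. Small nucleolar RNAs, a class examined after the data were seen, had a median of 0.29 over 84 kept genes, above all 10000 matched random lists, against 0.03 with ethanol, at percentile 31.0. The 66 of them bright on all arrays had medians of 0.29 with acetaldehyde and -0.04 with ethanol, the latter at percentile 0.070. SNORD42A was 1.90-fold higher and SNORA14B 1.89-fold. The aldehyde oxidase AOX1 was 1.86-fold higher, and the median of the ethanol and aldehyde metabolism list was -0.10. In that list the retinaldehyde dehydrogenase ALDH1A3 was at 0.93, but its intensity of 716 lay between control 2 (376) and control 1 (1174), and its other probe set was at -0.11.

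The other lists had acetaldehyde medians within 0.21 of 0, and the YAP (percentile 99.9), ATF4 (99.8), cholesterol (0.125), immediate early (0.160), Notch (0.360), luminal (0.415) and interferon (0.540) lists lay in the lowest or highest 1% of matched random lists. For control 2 against control 1 these lists stood at percentiles 94.2, 0, 0, 100, 91.4, 0.96 and 17.5, in the same order. ATF4 targets had a median of 0.13, with 14 of 21 genes above control 2, including SLC7A11 at 0.80, and a median of -0.61 against control 1. YAP targets were at 0.17 (NT5E 0.71), Fanconi genes at 0.13 (FANCL 0.36), heat shock at 0.11, p53 targets at 0.10 (PLK3 0.54), the unfolded protein response at 0.10 and aryl hydrocarbon targets at 0.09. NF-kB inflammation was at 0.08 (IL1B 0.63), proliferation at 0.07, NRF2 at 0.07 and histones at 0.04. Retinoid targets were at -0.21, interferon response at -0.21, luminal genes at -0.16 (ELF3, an epithelial transcription factor, -0.76), immediate early genes at -0.15 (FOS -0.66), Notch genes at -0.15, non-epithelial markers at -0.14 (CD14 -0.61), cholesterol synthesis at -0.13 (INSIG1 -0.56) and fatty acid synthesis at -0.11. Medians for Wnt genes (-0.05), apoptosis regulators (-0.04), growth factor signalling (-0.02), mitochondrial respiration (-0.02), the basal list (-0.01, with KRT14 at -0.95), metallothioneins (0.01), the mesenchymal list (0.01), one-carbon genes (0.01), hypoxia (0.02) and ribosomal proteins (0.00) lay within 0.05 of 0. Against control 1 the medians turned to 0.22 for immediate early genes, 0.0513 for fatty acids and 0.0431 for Notch.

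**Figure D2:**
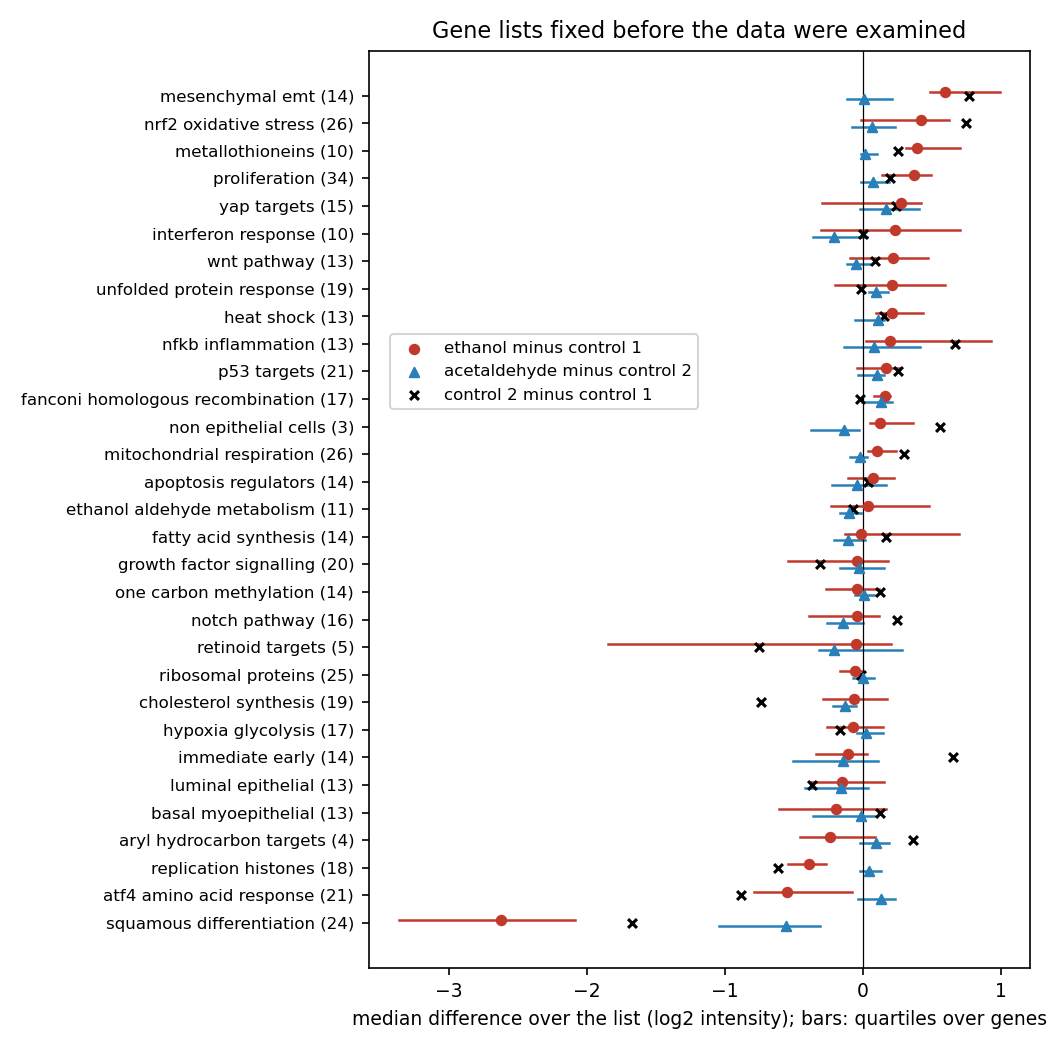
Median log2 intensity difference of each of the 31 gene lists for ethanol minus control 1 (red circles), acetaldehyde minus control 2 (blue triangles) and control 2 minus control 1 (black crosses), with bars from the lower to the upper quartile over genes and the number of kept genes in brackets. The squamous list stands lowest, at -2.62, -0.56 and -1.67.

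The exposures were then compared with each other. Across 10373 genes the matched differences, which share no array, correlated with r = 0.388 and rho = 0.350, across genes that are not independent replicates, and with a slope of 0.18 for acetaldehyde on ethanol. By size alone, which keeps the pairs free of shared arrays, 219 genes were at least 2-fold lower with ethanol, and 87.7% of them were below control 2 with acetaldehyde, against 49.3% of all genes. Of the 22 genes at least 2-fold lower with acetaldehyde 16 were among the 219, among them KRT10, CRABP2 and KRT16, against 0.464 for independent lists. Of the 121 genes at least 2-fold higher with ethanol, 70.2% were higher with acetaldehyde, against 50.7% of all genes. Under the range rule, which brings both controls into both lists, 13 of the 18 genes lower with acetaldehyde were among the 146 lower with ethanol. Exchanging control 2 and acetaldehyde at random in each gene gave a similar share, on average 6.42 of 10.1. The range rule thus gives most of such an overlap by itself, and the 13 genes are not read as evidence of a shared response. SERPINA1 (2.20 with ethanol, -0.02 with acetaldehyde), TLR2 (2.43 and 0.32), SLCO2A1 (1.89 and -0.11), TGM2 (2.50 and 0.59) and the ethanolamine kinase ETNK2 (1.28 and -0.63) were furthest apart in favour of ethanol. At the other end were SPRR3 (-6.16 and -0.09), SPINK7 (-5.29 and -0.45), the amino acid transporter SLC6A14 (-4.48 and 0.06), SPRR1A (-5.11 and -1.07) and POF1B (-4.38 and -0.52). Control 2 was already below control 1 for each of these 5 genes (SPRR3 -4.77, SPINK7 -4.17, SLC6A14 -4.53, SPRR1A -2.30, POF1B -3.21), and SLC6A14 was at 112 with ethanol against 108 in control 2. These differences between the exposures were not tested, since a fit with both experiments and both exposures leaves no residual degrees of freedom, and the doses of the compounds differed. Against the other experiment's controls the correlation was -0.607, a value that contains the difference between the controls with opposite signs.

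Transcripts that differed by similar amounts with both compounds were looked for in a fit with the experiment as a block. CRABP2 was lowest by p, 3.61-fold lower with ethanol and 3.10-fold lower with acetaldehyde (mean -1.74, SE 0.12; limma, unadjusted p = 5.08e-05). The membrane protein PLXDC2 (-1.19 and -1.08), the prominin PROM2 (-1.44 and -1.09) and KRT10 (-4.20 and -2.44) followed, as did PGLYRP4, at an intensity of 68.1 with ethanol against 154 and of 113 with acetaldehyde against 226. On the higher side stood INHBA (1.08 and 1.02), the matrix glycoprotein THBS1 (1.11 and 0.99), SCARNA9 (1.46 and 1.08), SCARNA9L (1.19 and 0.93) and SNORD42A (0.92 and 0.93). No gene passed an adjusted p of 0.05 in limma (0 of 10373, smallest adjusted p 0.495), while 1024 had an unadjusted p under 0.05, against 519 by chance. A fit without the block that left out control 2 gave 36 genes.

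Over the lists, 14 of the 24 squamous genes passed when adjusted over the list alone, against 0 over all genes tested, with KRT10, KRT1 and S100A7 smallest (limma, adjusted p = 0.00741). CRABP2 passed in the retinoid list of 5 kept genes (limma, adjusted p = 0.000254 when adjusted over the list alone, against 0.495 over all genes). Also past the threshold over their own lists were 4 basal genes including DSG3, KRT14 and LAMB3, the immediate early genes JUNB and ZFP36, ELF3 in the luminal list and NT5E in the YAP list. Adjusting within each list does not correct for the 31 lists examined, and 0 of these genes passed over all genes tested. Set tests with camera in limma at a preset correlation passed for 10 of 31 lists: lower for squamous differentiation (adjusted p = 1.41e-18), replication histones (0.00300), cholesterol synthesis (0.0367), immediate early (0.0383), luminal (0.0449), ATF4 (0.0449) and Notch (0.0449), and higher for proliferation (0.000142), NRF2 (0.0428) and the mesenchymal list (0.0428). The preset was 0.01, whereas the estimated correlation was 0.778 for histones, 0.681 for squamous and 0.483 for proliferation. Among these lists only cholesterol synthesis (-0.0526) and Notch (-0.0667) were estimated below the preset. For lists of correlated genes the preset p-values are too small, so passing at the preset is weak evidence. With an estimated correlation none of these lists passed camera (adjusted p = 0.784 with an estimated correlation for each). That form of camera takes its degrees of freedom from the fit, here 1, so it could hardly pass any list and decides nothing. For cholesterol synthesis the unadjusted p in camera rose from 0.00473 to 0.201, although its estimated correlation was -0.0526. No list passed fry, which tests whether the genes of a set move on balance one way (smallest adjusted p 0.288). Since fry also rests on the 1 residual degree of freedom, it could hardly pass any list, and this negative result decides nothing. Even the squamous list had an unadjusted p of 0.258 in fry. The ATF4 median was negative with ethanol and positive with acetaldehyde, as was that of the histones, and the tests weigh both exposures together. For fatty acid synthesis camera pointed down although the mean with ethanol was positive, and it pointed down for ethanol and aldehyde metabolism, interferon response and apoptosis regulators although their medians with ethanol were positive. Growth factor signalling with acetaldehyde had a median of -0.02 and a mean of 0.03.

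Against both controls together, which sets arrays of separately normalized pairs side by side, KRT10 stood at -4.34 with ethanol and at -2.30 with acetaldehyde on the log2 scale, in limma fits with 0 genes past an adjusted p of 0.05 for either compound. KRT10, PI3, CALB1, SPRR1B and S100A9 had the smallest p among lower genes with ethanol, and SLCO2A1, ANGPTL4, the fucosidase FUCA1, IL31RA and the phosphatase PLPP4 had the smallest p among higher genes. With acetaldehyde the smallest p were those of KRT10, CRABP2, KRT16, PGLYRP3 and PI3 among lower genes, and of SCARNA9, ANGPTL4, SUGCT, AOX1 and SNORA14B among higher ones. The smallest adjusted p in limma was 0.281 for ethanol and 1.00 for acetaldehyde, with 142 and 32 genes at an unadjusted p under 0.05, both fewer than the 519 given by chance. With the spread of the blocked fit in place of that between the controls, 2586 genes had an unadjusted p under 0.05 for ethanol, and 0 passed the adjustment in limma. That spread leaves out the difference between the experiments, which the contrast with both controls still contains. The count of 2586 is therefore inflated by construction and is not comparable with the 519 given by chance. Without the filter on dim genes limma called 9 genes for ethanol.

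**Figure D3:**
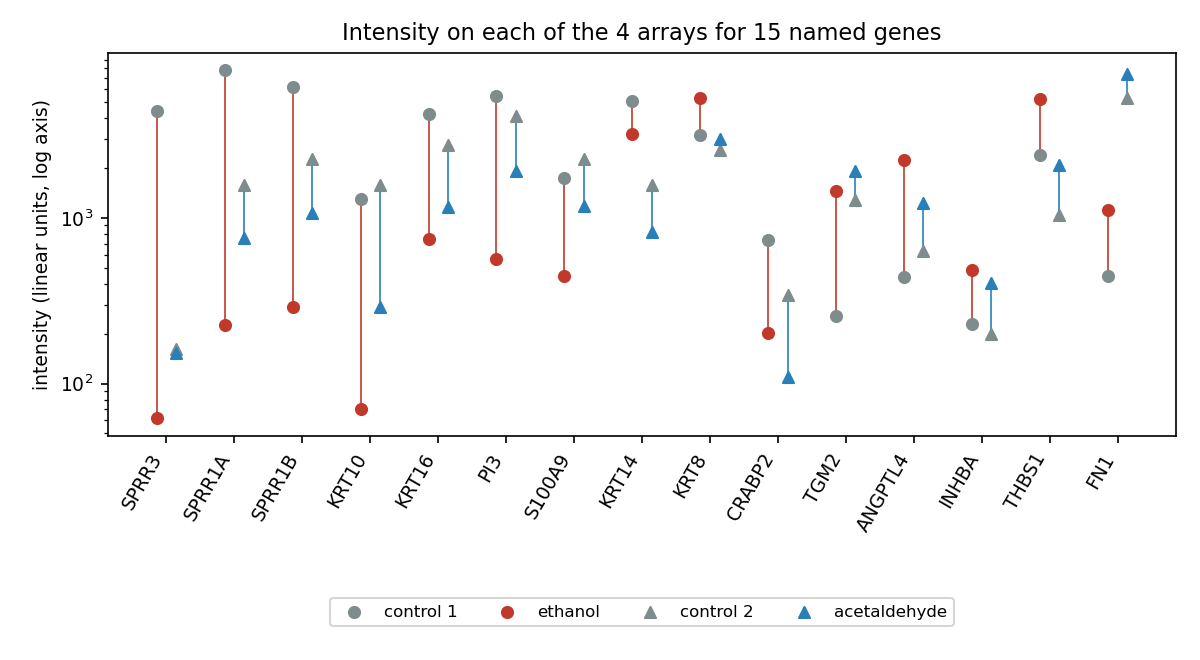
Intensity (linear units on a log axis) of 15 genes on the 4 arrays, with grey circles for control 1, red for ethanol, grey triangles for control 2, blue for acetaldehyde, and lines joining each exposed array to its control. KRT10 is at 1298 and 1571 in the controls and at 70.5 with ethanol and 290.0 with acetaldehyde, while SPRR3 is at 4404 in control 1 alone.

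The unexposed cultures differed from each other more than either exposed culture did from its control. IL1R2, the decoy interleukin-1 receptor, was 37.4-fold higher in control 2 than in control 1, the aldo-keto reductase AKR1B10 17.8-fold, the selenium transporter SELENOP 13.1-fold, the kinase PDK4 12.4-fold and FN1 12-fold. The microfibril protein MFAP5 was 44.2-fold lower in control 2, the epidermal caspase CASP14 43.1-fold, the kallikrein KLK5 29.7-fold, SPRR3 27.2-fold and the carboxypeptidase CPA4 26.0-fold. In all, 944 genes were at least 2-fold apart, 441 higher and 503 lower in control 2, against 340 in the ethanol pair and 25 in the acetaldehyde pair by size alone. The separate normalization of the pairs enters this comparison. Of the genes named here all but PDK4, FN1 and SPRR3 had their lower value under 155, and MFAP5 (31.3 in control 2) and SELENOP (12.1 in control 1) lay below the lower quartile of that array, so the sizes of their folds are uncertain.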

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

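Of the tests in this part, those of symmetric noise and of small RNA recovery were chosen only after the result was seen.

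The medians of the ATF4 amino acid response list had opposite signs in the exposures, with 18 of 21 genes lower with ethanol and 14 of 21 higher with acetaldehyde, and its medians differed by -0.677 (log2). That difference was not tested, control 2 was itself at -0.89 against control 1 over this list, and with the other experiment's control both signs turned, to 0.25 with ethanol and -0.61 with acetaldehyde. Ethanol is set against control 1 and acetaldehyde against control 2, so a gap between the controls could by itself give opposite signs. ASNS, asparagine synthetase, was at -0.80 with ethanol and 0.71 with acetaldehyde, and SLC7A11 at -1.18 and 0.80.

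A signal also appeared in data outside the gene comparisons, in the lowest-numbered probe sets, which the annotation used here does not list. Of 4203 such probe sets 1922 were bright enough to be kept, and 88 were at least 2-fold higher with ethanol than in control 1 against 5 lower, while 78 were higher with acetaldehyde than in control 2 against 3 lower. Scaling alone is argued against by the lower of the medians after cyclic loess, 0.0749 (SE 0.00865), although loess reduced both medians from 0.15 and 0.11. Symmetric noise, independent between the pairs, is argued against, since the differences of the pairs, which share no array, correlated at 0.518 over the 1922 probe sets. The ratio of higher to lower probe sets, at least 17.6, decides nothing, because it is itself what drew attention to them. Better recovery of small RNA in both exposed cultures is argued against by the small nucleolar RNAs, whose median was 0.0330 (SE 0.0434) with ethanol and 0.290 with acetaldehyde. What these probe sets measure is not given in the annotation used here, so they are not read as transcripts of genes. Whether exposure or the handling of the cultures moved them stays open, since control 2 was also at least 2-fold above control 1 for 157 of them and below it for 53.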

How the results depend on the processing

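Of the alternatives, median centring for the blocked fit, and median centring and quantile normalization for the lists, were chosen only after the data were seen. Median centring, quantile normalization, cyclic loess and dropping the range rule kept the matched counts within 1.5 times of 234 genes for ethanol and 20 for acetaldehyde. Quantile normalization gave 64 higher and 139 lower genes for ethanol and 5 and 22 for acetaldehyde. Centring moved the median of control 2 minus control 1 over all genes from 0.06 to -0.15. At a 1.5-fold threshold the counts were 692 (398 higher, 294 lower) and 137 (59 and 78), and 2889 between controls. Without the dim filter they were 38 for acetaldehyde (14 and 24) and 1537 between controls, and with the upper-quartile filter 138 for ethanol, fewer genes being tested. With all probe sets acetaldehyde gave 105 (83 and 22), which adds probe sets that name no gene. Against the other experiment's control the counts were 629 (365 and 264) for ethanol and 671 (321 and 350) for acetaldehyde, and against the mean of both controls 216 (69 and 147) for acetaldehyde. The correlation of the responses turned to -0.607 with crossed controls, and it was 0.320 without the dim filter and 0.379 after cyclic loess. Crossing pairs brings the difference between controls into each value by construction. It also turned list medians: with ethanol NRF2 -0.35, metallothioneins -0.0242, ATF4 0.25, histones 0.26, cholesterol 0.53, mesenchymal -0.28, luminal 0.88, basal 0.12, hypoxia 0.38 and YAP -0.0843, and with acetaldehyde ATF4 -0.61, fatty acids 0.0513, immediate early 0.22 and Notch 0.0431. Without the dim filter the ethanol medians were 0.0855 for basal and -0.0720 for Wnt; the cause was not tested. Of the lists, 0 passed camera with an estimated correlation, which could hardly pass any list with 1 residual degree of freedom. At the preset correlation, which gives p-values that are too small for lists of correlated genes, 3 passed without the block, and 8 or 9 under the other scalings and filters. The squamous medians stayed below 0 in every alternative run, from -2.67 to -1.11 with ethanol and from -2.40 to -0.54 with acetaldehyde. For ethanol against both controls limma called 9 genes without the dim filter (smallest adjusted p 1.81e-06), 1 with an intensity trend and 2 with a robust trend; the cause was not tested. Over its alternatives the smallest adjusted p ran from 1.81e-06 to 0.589. Leaving out each array in turn, for either exposure, gave 0 to 36 genes in limma, with 36 when control 2 was left out (smallest adjusted p 0.00752, where both exposures are set against control 1 alone) and 0 for each other array. Acetaldehyde against both controls gave 0 under each alternative. Leaving out a control there leaves no residual degrees of freedom, so those fits give values with no test. Of the named gene values 1162 stayed within their spread and 358 moved. Signal near background limits genes under the dim filter.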

Other observations

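Of the tests in this part, the share of epithelial cells, the state of the unexposed cultures and the 5 gene groups of the next paragraph were chosen only after the result was seen.

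Other genes of stratified epithelium, grouped after their values were seen, lay below control with the squamous genes. All 14 kept epithelial transcription factors were lower with ethanol (median -1.26) and 13 with acetaldehyde (median -0.29), including EHF (-3.28 and -0.69), ZNF750 (-2.93 and -1.09), GRHL1 (-2.75 and -0.44) and GRHL3 (-1.65 and -0.82), regulators of epidermal differentiation. Of 15 genes of skin barrier lipids 14 were lower with ethanol (median -0.84) and 12 with acetaldehyde (median -0.34), among them the omega-hydroxylase CYP4F22 (-3.59 and -0.52) and the lipoxygenase ALOX12B (-1.88 and -0.63). Desmosome and tight junction genes had medians of -0.81 and -0.25 over 18 genes, with DSP at -1.02 and -0.42 and CLDN1 at -1.08 and -0.74. Epidermal serpins and kallikreins had medians of -2.25 and -0.35 over 15 genes. All 17 kept genes of matrix and TGF-beta ligands were higher with ethanol (median 0.80), and 10 were with acetaldehyde (median 0.11), with ADAM12 at 1.37 and 0.11, SPOCK1 at 1.41 and -0.09 and FSTL1 at 0.80 and 0.58. Control 2 was also below control 1 in the transcription factors (-0.88), junction genes (-0.51), serpins and kallikreins (-2.22) and, by just over 1 log2 unit, the barrier lipids, and close to it in the matrix group (0.06). The groups were chosen from genes already seen to differ, so their counts and medians follow from that choice. Neither these nor their camera results are independent evidence. With an estimated correlation the adjusted p of camera in limma was 0.404, but with 1 residual degree of freedom that form could hardly pass any group.

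The lower squamous differentiation genes may reflect an effect of exposure or a difference between cultures. Scaling is argued against, since the ethanol median stayed at -2.60 or lower under 3 scalings. The 26 basal and luminal genes went both ways, with a median of -0.17 (SE 0.16 over genes). As a set they did not fall with ethanol as the squamous list did. A loss of epithelial cells is not decided by that median, since normalized arrays of 1 epithelial line would not show fewer cells. A change limited to the epidermal differentiation complex, the gene cluster that holds the SPRR and S100 genes, is argued against by the 15 members outside it, with a median of -2.56 (SE 0.31). The state of the unexposed cultures cannot be told apart from exposure, since control 2 was at -1.67 (SE 0.46) against control 1 over the same list and each arm is 1 culture. Single members differ in this, and LCN2, KRT10, S100A9, PI3 and KRT16 had controls within 0.64 of each other. KRT1, S100A7 and S100A8 were higher in control 2 than in control 1, and lower in each exposed array than in its own control. With acetaldehyde, however, KRT1, S100A7 and S100A8 lay between the controls, so there they do not set exposure apart from the state of the cultures.

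The larger number of genes 2-fold apart with ethanol than with acetaldehyde may come from dose, compound or culture. A pair that is noisier throughout is argued against, since scaling the acetaldehyde differences up to the central spread of ethanol gave 111 genes against 340. Trends across intensity are argued against by the counts after cyclic loess, 231 with ethanol and 21 with acetaldehyde. A control 1 culture that was more differentiated than control 2 stays open, as do the compounds and their unequal doses, none of which 1 array per arm can separate.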
